A study of Homo sapiens with 15 samples.

How the data were processed

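Messenger RNA was sequenced from Mia PACA-2 cells, an established human pancreatic cancer line. The 15 libraries fell into 3 groups of 5, taken from the sample titles: control cells, cells overexpressing cytidine deaminase (CDA) and cells overexpressing the E67Q form of the enzyme (CDA_E67Q). Each title gives a pool number from 1 to 5. The labels do not say what a pool is or whether the pools came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Per the labels' protocols, RNA was purified on RNeasy columns, mRNA was selected with poly-T beads from 1 µg of total RNA, and libraries were made with an NEBNext Ultra kit. Per the submitters' processing notes, bcl2fastq, FastQC, Trimmomatic and Salmon were used with the GRCh38 build, and no versions were given. Whether reads were assigned by strand is not given in the sources used here, so overlapping and antisense genes, and near-identical copies such as histone and ribosomal protein genes, are uncertain.

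The authors deposited 2 tables of 16887 genes, 1 with the control and CDA libraries and 1 with the control and CDA_E67Q libraries. The tables are named as read counts, but the deposited values are on a log2 scale: they are not whole, and every gene with no read holds the same floor, 6.65 in the first table and 6.17 in the second. They have the form of variance-stabilised normalised counts. The step from Salmon's output to these values is not given in the sources used here. Such values compress differences between low genes. They were turned back into normalised counts by squaring the difference between 2 to the power of the value and 2 to the power of the floor, and dividing by 2 to the power of the value. The 5 control libraries stand in both tables. After this step their values differed by no more than 1 factor per gene and 1 factor per library, with a largest residual of 1.36e-08 log2 over 11013 genes. These factors put all 15 libraries on 1 scale for the 13917 genes with a read in the controls. The other 2970 genes were left out of that scale, and 2 gene names had been turned into dates. Of the 16887 names, 16667 matched current gene symbols.

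The edgeR count test fixed for these comparisons could not be used, because the values were not counts. Whole reads could not be recovered: a mean of 34.9% of the normalised counts under 12 in a library lay within 0.05 of a whole number of reads (range 23.3 to 40.1%). The size of 1 read, read from the most frequent low values, gave an estimated 21.4 to 31.4 M reads per library. These estimates have no counting interval.

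Tests used limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2 of the normalised count plus a pseudocount of 1, which understates the change of low genes. Genes with a normalised count of at least 10 in at least 5 libraries were tested. CDA and CDA_E67Q were each compared with the control within their own table of 10 libraries, because the tables had been normalised separately. CDA and CDA_E67Q were compared with each other in 1 fit over the 15 libraries on the common scale. No block was used, p-values were 2-sided, and the Benjamini-Hochberg adjusted p threshold was 0.05. For the CDA transcript and for mean list scores, 2-sided exact permutation tests were also run. With 5 against 5 libraries the smallest exact p is 0.00794. Gene positions came from GENCODE annotation on GRCh38. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and plots.

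The groups, the main comparisons, the filters' kind, the gene lists, the rule for naming genes and most alternatives were set before the data were examined. The back-transform, the unit of the test, the pseudocount and the minimum of 10 were set after the unit of the tables was known. The rule named CDA in every library. It also named up to 12 genes with the largest and 12 with the smallest log2 difference among genes past the threshold whose groups did not overlap. From each list described with no member past the threshold, it named the 2 members with the smallest p. Genes chosen in another way are said to be so where they stand.

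Of 33 gene lists, 29 had at least 5 tested genes. They covered pyrimidine metabolism, nucleoside transport and drug efflux, purine and folate one-carbon metabolism, DNA replication, the replication stress response, homologous recombination, other DNA repair, p53 target genes, G2/M and mitosis, CDK inhibitors and G1/S cyclins, and replication-dependent histones. They also covered interferon-stimulated genes, NF-kB and cytokine genes, the integrated stress and unfolded protein responses, autophagy and lysosome, NRF2 targets, MAPK output, MYC targets, immediate early and heat shock genes, hypoxia and glycolysis, oxidative phosphorylation, ribosomal proteins, cholesterol biosynthesis, fatty acid synthesis, and collagens and extracellular matrix. The others held markers of epithelial, mesenchymal, fibroblast and neuroendocrine cells. Lists were tested with limma's camera at a preset correlation between genes of 0.01, then with an estimated correlation, and with fry. CDA itself was left out of its list. The lists of mitochondrially encoded genes and of acinar, immune and endothelial markers had too few tested genes.

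The procedure was tested on simulated data with the real genes' means and spreads, with 50 genes changed at each of 4 sizes. In the comparison of CDA with control, over 11341 genes, it recovered 10% of genes changed 1.5-fold, 28% at 2-fold, 74% at 4-fold and 88% at 8-fold, with 10 false calls. For CDA_E67Q against control, over 11341 genes, the shares were 6, 36, 74 and 86%, with 10 false calls. For CDA against CDA_E67Q, over 11588 genes, they were 6, 36, 74 and 94%, with 8 false calls. A DNA replication list shifted by 0.5 log2 was called in each. The simulated genes vary independently and without pools, so these data give no rate of false calls for lists in the real libraries. They also do not give the share of changed genes that would be recovered there. In the real libraries CDA was 26.2-fold higher with CDA and 34.0-fold with CDA_E67Q. It did not pass the threshold by limma without pool number in the fit.

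Pool numbers were checked by correlating each library's deviations from its group means over genes. Across CDA and CDA_E67Q, same-numbered libraries correlated at 0.33 to 0.89 in 5 of 5 pairs, and 10 of 10 libraries correlated best with their own number. The numbers, which come from the titles, were therefore taken as pairing CDA with CDA_E67Q. The main fits used no block, so differences between pools stayed in their error and can hide differences between groups. An absence of calls in them does not show that the groups are alike. Results with pool number as a block are given beside them. No pair of libraries in a group was near-identical: the smallest SD of a pair's difference was 0.90 log2. Alternatives covered scaling, the low-value filter, the pseudocount, the libraries in the fit, the replicate block, the deposited values without back-transform, leaving out pool 5 and leaving out each library in turn.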

Results

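The transcriptomes of 15 Mia PACA-2 libraries were measured by sequencing of polyadenylated RNA. The line was studied as control cells, as cells overexpressing cytidine deaminase (CDA), which converts cytidine and deoxycytidine to the uridine forms and inactivates cytidine analogue drugs, and as cells overexpressing CDA_E67Q, in which a glutamate needed for catalysis is replaced. Each group held 5 pools. The estimated depth was 25.4 ± 3.88 M reads in the control, 24.4 ± 3.19 M in CDA and 23.7 ± 3.05 M in CDA_E67Q (mean ± SD, n = 5), and 12508 to 13090 genes were detected per library. Levels below are normalised counts, as mean ± SD of 5 libraries per group.

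Libraries with the same pool number resembled each other more than libraries of the same group. Pool number accounted for 65.3% of the variance of 11588 genes, against 28.6% by chance, and group for 6.10%, against 14.3% by chance. The chance share for group ignores pool number. By limma, 5217 genes (45%) differed between pool numbers once group was in the fit, and 1 gene, CDA, differed between groups once pool number was in the fit (adjusted p = 0.00534). The 3 libraries of pool 5 stood apart from the other 12 on the first principal component, which held 38.7% of the variance. In pool 5, mitotic and DNA replication genes were lower by camera (adjusted p = 0.0682 for both with an estimated correlation) and by fry (adjusted p = 3.02e-07 and 6.27e-07). Interferon-stimulated and cytokine genes were higher (adjusted p = 0.426 and 0.234 with an estimated correlation, and 0.0115 and 0.000202 by fry). Fry, unlike camera, does not set a list against the other genes, and many other lists also passed by fry in pool 5. Each pool number held 1 library of each group, so no test could be run within a number.

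**Figure D1:**
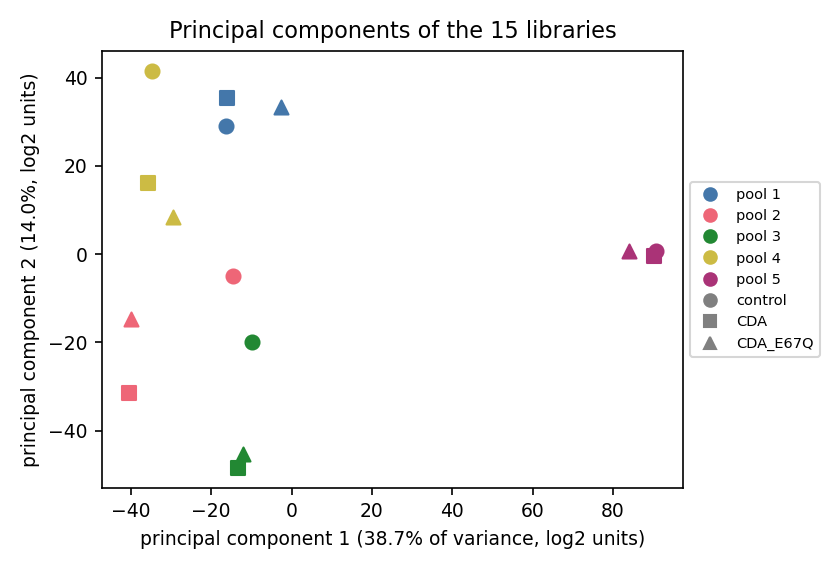
Principal components 1 and 2 of log2 normalised counts in the 15 libraries, with colours for pool numbers and symbols for groups. The 3 libraries of pool 5 lie at the far right of component 1 (38.7% of variance), and component 2 holds 14%.

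The CDA transcript was higher in both overexpressing groups than in any control library. The gene lies on chromosome 1 at positions 20588948 to 20618908, plus strand, in GRCh38. In the control it was present at 133 ± 139, from 9.91 in pool 4 to 312 in pool 3, with 16.7, 250 and 77.2 in pools 1, 2 and 5. In the CDA group it reached 2154 ± 1794, with 1141, 5222, 2205, 775 and 1429 in pools 1 to 5. The log2 difference was 4.71 (SE 0.917, 95% interval 2.59 to 6.82), a 26.2-fold higher level, and same-numbered pools differed 7.06 to 78.2-fold. In the CDA_E67Q group it reached 2504 ± 1659, with 1334, 1717, 5383, 1648 and 2439 in pools 1 to 5, against 131 ± 137 in the control of that table. That log2 difference was 5.09 (SE 0.862, 95% interval 3.10 to 7.07), a 34.0-fold higher level, and same-numbered pools differed 6.96 to 169-fold. Each difference had an exact permutation p of 0.00794, the smallest that 5 against 5 libraries can give, with 5 of 5 libraries higher. Across all genes tested with limma, CDA did not pass the threshold in either comparison (adjusted p = 1.00 for CDA and 0.802 for CDA_E67Q) without pool number in the fit. It passed with pool number as a replicate block and all 15 libraries in 1 fit (adjusted p = 0.00987 and 0.00419), and on the deposited values with the block (0.00220 and 0.00111), settings chosen after the data were seen. Over 22 alternatives each, 2 passed, and the adjusted p ran from 0.00220 to 1.00 for CDA and from 0.00111 to 1.00 for CDA_E67Q. On the common scale CDA was at 2154 ± 1794 in the CDA group and 2547 ± 1688 in the CDA_E67Q group, a log2 difference of -0.38 (95% interval -2.17 to 1.42, exact p = 0.532). The values are gene totals and do not separate wild-type from E67Q transcripts.

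**Figure D2:**
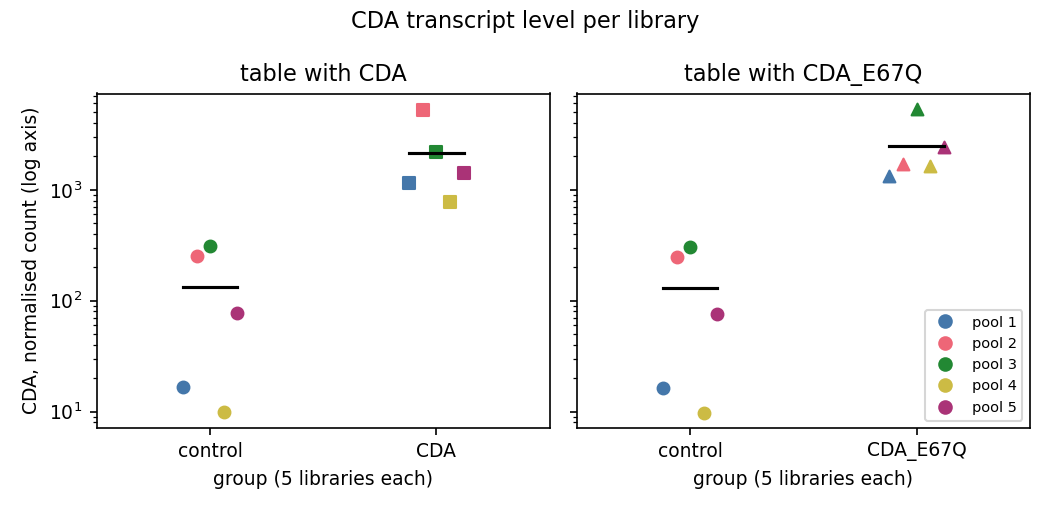
Normalised count of the CDA transcript per library on a log axis, for the control and CDA libraries of the first table and the control and CDA_E67Q libraries of the second, coloured by pool number, with horizontal lines at group means. The 5 CDA libraries lie between 775 and 5222 and the 5 CDA_E67Q libraries between 1334 and 5383, all above the control libraries, whose highest values are 312 and 307.

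The comparison of CDA with control asked what overexpression of the enzyme did to the transcriptome, in a study concerned with replicative stress and DNA-targeting drugs. Interferon-stimulated genes, which respond to viral nucleic acid sensing, were higher with CDA in 33 of 40 tested members, with a median log2 difference of 0.33 (camera adjusted p = 7.17e-05). The call was lost with the correlation estimated from the data (adjusted p = 0.829 with an estimated correlation). The mean deviation of these genes differed most in pool 3 (0.84 log2 with CDA, -0.52 in the control), then in pool 4 (-0.66 and -1.16) and pool 1 (-0.49 and -0.71), and hardly in pools 2 (0.47 and 0.48) and 5 (0.96 and 1.00). MX2 stood at 425 ± 77.5 against 278 ± 197 and OAS2 at 108 ± 72.4 against 45.9 ± 24.0. NF-kB and cytokine genes were higher in 14 of 18 members, with a median of 0.26 (camera adjusted p = 0.00711, and adjusted p = 0.793 with an estimated correlation). BIRC3, an inhibitor of apoptosis, stood at 1066 ± 788 against 601 ± 261, and the neutrophil chemokine CXCL8 at 2671 ± 805 against 2070 ± 449. The interferon call ended without CDA replicate 5 (median 0.17, adjusted p = 0.245) or control replicate 4 (median 0.063, adjusted p = 0.435). The NF-kB call ended without CDA replicate 5 (median 0.24, adjusted p = 0.0906), control replicate 3 (median 0.19, adjusted p = 0.0958) or control replicate 4 (median 0.24, adjusted p = 0.0862).

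Genes of the dividing cell were also placed higher with CDA by camera. DNA replication genes were higher in 40 of 48 members, with a median of 0.13 (camera adjusted p = 0.0297, and adjusted p = 0.829 with an estimated correlation). The replication licensing factor CDT1 stood at 3762 ± 735 against 2860 ± 330, and the clamp loader subunit RFC4 at 1471 ± 257 against 1304 ± 285. G2/M and mitosis genes were higher in 37 of 39 members, with a median of 0.13 (camera adjusted p = 0.0229, and adjusted p = 0.829 with an estimated correlation). ECT2, needed for cytokinesis, stood at 5256 ± 1313 against 4014 ± 1123, and the checkpoint gene BUB3 at 5684 ± 1848 against 4827 ± 1090. Replication-dependent histones were higher in 15 of 22 members, with a median of 0.44 (camera adjusted p = 0.0115, and adjusted p = 0.829 with an estimated correlation). H3C4 stood at 39.9 ± 5.05 against 28.7 ± 9.86 and H1-5 at 25.4 ± 12.8 against 13.3 ± 8.37. MYC target genes were higher in 24 of 30 members, with a median of 0.086 (camera adjusted p = 0.0487, and adjusted p = 0.829 with an estimated correlation). The ribosome biogenesis genes RRP12 and BOP1 stood at 2399 ± 262 against 2113 ± 445 and 5847 ± 1476 against 4898 ± 1475. Hypoxia and glycolysis genes were higher in 24 of 32 members, with a median of 0.11 (camera adjusted p = 0.0487, and adjusted p = 0.829 with an estimated correlation). The peptide hormone gene ADM stood at 167 ± 183 against 65.2 ± 27.4, and hexokinase HK2 at 1681 ± 289 against 1403 ± 410.

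The calls changed with the libraries in the fit. Some medians kept a similar size, and others shrank or changed sign. Without CDA replicates 2 and 4 in turn, the DNA replication median was 0.027 and 0.041, and the G2/M median -0.00073 and 0.024. The MYC median was -0.031 without CDA replicate 4, 0.027 without control replicate 2 and 0.029 without control replicate 5. The histone median was 0.013 without control replicate 5, and the hypoxia median 0.035 without CDA replicate 2. The DNA replication call ended without CDA replicate 1 (adjusted p = 0.385), 2 (0.742), 3 (0.172) or 4 (0.820), and the G2/M call without CDA replicate 1 (0.377), 2 (0.868), 3 (median 0.13, adjusted p = 0.0849) or 4 (0.679). Without control replicate 5 both lists were called lower with CDA, with medians of -0.12 (adjusted p = 0.0442) and -0.13 (0.0347). That fit kept the CDA library of pool 5, which was low in both lists. The histone call ended without CDA replicate 1 (median 0.40, adjusted p = 0.0930), 3 (0.0990) or 4 (0.173) and control replicate 3 (0.148) or 5 (0.934). It also ended with a filter of 1 per M reads in 5 libraries (median 0.15, adjusted p = 0.436). The MYC call ended without CDA replicate 1 (adjusted p = 0.127), 3 (0.0947) or 4 (0.900) and control replicate 2 (0.913), 3 (0.263) or 5 (0.584). It also ended under upper-quartile scaling (adjusted p = 0.0503), equal totals (0.0537), no low-value filter (0.117), all 15 libraries in 1 fit without (0.0556) and with the block (0.0833), and deposited values (0.0538), and it was kept in 9 of 22 alternatives. The hypoxia call ended without CDA replicate 2 (adjusted p = 0.574), 3 (0.0632) or 4 (median 0.12, adjusted p = 0.173) and control replicate 1 (median 0.11, adjusted p = 0.0944), 3 (0.214), 4 (0.146) or 5 (0.140). It also ended with no low-value filter (0.169), all 15 libraries in 1 fit (0.0537) and deposited values (0.0538). With no low-value filter the DNA replication (0.0685), G2/M (0.0591) and NF-kB (0.0591) calls ended too. Without pool 5 in every group 7 lists were called, the histone (adjusted p = 0.0855) and MYC (0.0667) calls were lost, and the replication stress response (0.0480) and homologous recombination (0.0345) were gained.

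With all libraries and no block, the pathways nearest to the enzyme were not called with CDA. Pyrimidine metabolism genes were higher in 22 of 28 members (camera adjusted p = 0.301), with uridine-cytidine kinase UCK2 at 3567 ± 807 against 2970 ± 314 and CTP synthase CTPS2 at 1218 ± 292 against 1475 ± 527. Nucleoside transport and drug efflux genes were higher in 3 of 11 members (0.450), with the efflux pump ABCC3 at 193 ± 121 against 258 ± 136 and the equilibrative transporter SLC29A2 at 355 ± 58.7 against 395 ± 123. Replication stress response genes were higher in 30 of 41 members (0.377), with the checkpoint clamp gene RAD1 at 790 ± 97.7 against 687 ± 83.7 and the translesion polymerase REV3L at 661 ± 68.7 against 758 ± 154. Homologous recombination genes were higher in 20 of 24 members (0.157), with RAD51B at 162 ± 57.9 against 127 ± 37.6 and RAD54L at 909 ± 256 against 756 ± 294. For p53 target genes, 14 of 26 members were higher (0.502), with SESN2 at 614 ± 81.4 against 755 ± 168 and FBXO22 at 1215 ± 154 against 1077 ± 289. Some alternatives gained calls at the preset correlation. Homologous recombination was called higher without control replicate 3 (adjusted p = 0.00692) or 4 (0.0149), without CDA replicate 5 (median 0.34, adjusted p = 0.000206), without pool 5 (0.0345), and with deposited values and block (0.0444). The replication stress response was called higher without CDA replicate 5 (median 0.20, adjusted p = 0.000638) or pool 5 (median 0.11, adjusted p = 0.0480), and pyrimidine metabolism without CDA replicate 5 (0.00219). The fit without CDA replicate 5 kept the control library of pool 5. Pool 5 was low in homologous recombination, replication stress and pyrimidine genes (medians -0.92, -0.54 and -0.48 log2 against the other libraries). The calls from that fit therefore cannot be told from the pool 5 pattern. Without pool 5 in every group pyrimidine metabolism was not called. The p53 targets were called lower without control replicate 1 (0.0258). The remaining 17 lists were not called either, from the integrated stress response (0.102) to oxidative phosphorylation (0.707). With pool number as a block the integrated stress response was called lower (median -0.10, adjusted p = 0.0485, from 0.00103 to 0.936 over 26 alternatives, and adjusted p = 0.662 with the block and an estimated correlation). For p53 targets and cholesterol biosynthesis the median was above 0 while the mean and the test were below it.

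No gene passed the threshold for CDA against control. By limma 0 of 11341 genes were called, 32 had an unadjusted p under 0.05 (19 higher, 13 lower) where chance gives 567, and the groups did not overlap for 6 genes, 0.0529% against 0.794% by chance. These chance values take the libraries as exchangeable and ignore pool number, so lying below them does not show that the groups are alike. Other splits of these libraries gave a median of 316 genes under 0.05, and the real split gave 201 with pool number as a block. Of the list members, 0 passed when adjusted over all genes and 0 when adjusted over the list alone. By fry 0 lists were called (smallest adjusted p = 0.936). A set of 5 genes was chosen after their values were seen, for low unadjusted p. The actin-binding kinase substrate MARCKS stood at 381 ± 711 against 10.3 ± 8.35, and the LIM-domain gene LMCD1 at 36.0 ± 22.8 against 11.2 ± 1.92, with all 5 CDA libraries above all 5 controls. Transglutaminase TGM2 stood at 19030 ± 12866 against 6745 ± 2922, AVL9 at 1473 ± 573 against 2308 ± 344, and the protease gene KLK6 at 4293 ± 2945 against 8763 ± 2324. Their log2 differences were 3.74 (SE 1.20), 1.42 (SE 0.483), 1.32 (SE 0.487), -0.72 (SE 0.245) and -1.46 (SE 0.570).

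The comparison of CDA_E67Q with control asked the same of the altered enzyme. MYC target genes were higher with CDA_E67Q in 25 of 30 members, with a median log2 difference of 0.15 (camera adjusted p = 0.00337, and adjusted p = 0.964 with an estimated correlation). BOP1 stood at 6513 ± 1940 against 4806 ± 1458 and RRP12 at 2543 ± 795 against 2010 ± 428. Nuclear-encoded oxidative phosphorylation genes were higher in 44 of 51 members, with a median of 0.092 (camera adjusted p = 0.0452, and adjusted p = 0.964 with an estimated correlation). SDHB, a subunit of succinate dehydrogenase, stood at 3391 ± 554 against 2869 ± 145, and the ATP synthase subunit ATP5F1D at 4260 ± 569 against 3669 ± 392. The MYC call ended without CDA_E67Q replicate 2 (adjusted p = 0.247) or 4 (0.201) and control replicate 2 (0.224) or 5 (0.0893). The oxidative phosphorylation call ended without CDA_E67Q replicate 2 (median -0.053, adjusted p = 0.247), control replicate 3 (0.0967) or control replicate 5 (median -0.0099, adjusted p = 0.834), and under upper-quartile scaling (0.0593), equal totals (0.0762) and no low-value filter (0.0812). Without pool 5 in every group 3 lists were called, with hypoxia and glycolysis gained (0.0479).

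Interferon-stimulated genes were higher with CDA_E67Q in 24 of 39 members and were not called (camera adjusted p = 0.50), with OAS3 at 117 ± 57.4 against 217 ± 116 and HERC6 at 77.9 ± 11.5 against 53.8 ± 31.8. DNA replication genes were higher in 30 of 48 members (0.760), with CDT1 at 3296 ± 391 against 2810 ± 325 and the polymerase subunit POLD1 at 3462 ± 1640 against 2527 ± 563. Pyrimidine metabolism genes were higher in 19 of 28 members (0.431), with thymidine phosphorylase TYMP at 60.8 ± 19.7 against 37.6 ± 14.5 and CAD, which starts pyrimidine synthesis, at 6264 ± 1422 against 5045 ± 632. Transport and efflux genes were higher in 6 of 10 members (0.791), with SLC29A1 at 2398 ± 503 against 2112 ± 276 and ABCC10 at 704 ± 220 against 609 ± 195. Replication stress response genes were higher in 22 of 41 members (0.791), with FANCM at 222 ± 61.7 against 308 ± 95.4 and REV3L at 608 ± 85.2 against 741 ± 152. Homologous recombination genes were higher in 13 of 24 members (0.956), with RAD54L at 950 ± 387 against 714 ± 279 and NBN at 451 ± 123 against 566 ± 190. For p53 targets 11 of 26 members were higher (0.791), with PPM1D at 453 ± 160 against 539 ± 136 and FBXO22 at 1229 ± 228 against 1082 ± 293. Leaving out 1 library gained calls at the preset correlation. Interferon-stimulated genes were called higher without control replicate 5 (median 0.41, adjusted p = 0.000514) or CDA_E67Q replicate 4 (median 0.32, adjusted p = 0.0311). DNA replication genes were called higher without CDA_E67Q replicate 5 (median 0.26, adjusted p = 1.09e-05) and lower without control replicate 5 (median -0.20, adjusted p = 0.000514). Pyrimidine metabolism was called higher without CDA_E67Q replicate 5 (0.00733), and the replication stress response lower without control replicate 5 (0.0457). Each fit without 1 pool 5 library kept that of the other group. Pool 5 was high in interferon-stimulated genes (median 1.14 log2 against the other pools). It was low in DNA replication (-1.10), replication stress (-0.54) and pyrimidine genes (-0.48). The calls from those fits therefore cannot be told from the pool 5 pattern. The remaining 20 lists were not called, from hypoxia and glycolysis (0.108) to other DNA repair (0.956). With pool number as a block the G2/M list was called higher (median 0.095, adjusted p = 0.0472, from 6.48e-07 to 0.984 over 26 alternatives, and adjusted p = 0.800 with the block and an estimated correlation). Its direction turned between leaving out CDA_E67Q replicate 5 (median 0.31) and control replicate 5 (median -0.19, adjusted p = 0.000514, called lower). Median, mean and test differed in sign for fatty acid synthesis, epithelial markers, the replication stress response, MAPK output, p53 targets, other DNA repair and homologous recombination.

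No gene passed the threshold for CDA_E67Q against control. By limma 0 of 11341 genes were called, 54 had an unadjusted p under 0.05 (30 higher, 24 lower) where chance gives 567, and the groups did not overlap for 9 genes, 0.0794% against 0.794% by chance. These chance values also ignore pool number. Other splits gave a median of 331 genes under 0.05, and the real split gave 265 with pool number as a block. Of the list members, 0 passed when adjusted over all genes and 0 when adjusted over the list alone, and by fry 0 lists were called (smallest adjusted p = 0.984). Again 5 genes were chosen for low unadjusted p after their values were seen. LMCD1 stood at 35.5 ± 10.0 against 11.6 ± 1.99, with all 5 libraries above the controls, and TLR3, a receptor for double-stranded RNA, at 9.09 ± 3.13 against 27.0 ± 12, with all 5 below. The cytoskeletal genes PDLIM5 and COTL1 stood at 1573 ± 682 against 668 ± 350 and 11636 ± 4174 against 5785 ± 2892, and the transcriptional inhibitor ID2 at 1852 ± 843 against 3716 ± 1742. Their log2 differences were 1.5 (SE 0.416), -1.45 (SE 0.517), 1.28 (SE 0.397), 1.09 (SE 0.355) and -0.98 (SE 0.340).

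Setting CDA against CDA_E67Q asked whether the catalytic change altered the response. Interferon-stimulated genes were higher with CDA in 32 of 41 members, with a median log2 difference of 0.25 (camera adjusted p = 0.00167, and adjusted p = 0.875 with an estimated correlation). OAS3 stood at 210 ± 140 with CDA against 118 ± 57.7 with CDA_E67Q, and IFI44 at 34.5 ± 40.5 against 15.0 ± 20.5. CDK inhibitors and G1/S cyclins were higher in 15 of 19 members, with a median of 0.20 (camera adjusted p = 0.0154, and adjusted p = 0.837 with an estimated correlation). E2F3 stood at 1188 ± 165 against 1025 ± 128 and the tumour suppressor RB1 at 1893 ± 466 against 1585 ± 276. Histones were higher in 19 of 25 members, with a median of 0.18 (camera adjusted p = 0.0379, and adjusted p = 0.875 with an estimated correlation). H4C5 stood at 19.4 ± 8.57 against 10.4 ± 6.43 and H4C8 at 12.8 ± 7.34 against 8.39 ± 8.54.

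Stress and housekeeping lists were called lower with CDA than with CDA_E67Q by camera at the preset correlation. All of these calls depended on CDA_E67Q replicate 2, whose normalised total was 28.4 M, the highest in its group. Without that library the stress and autophagy medians were -0.041 and -0.055 and were not called. Oxidative phosphorylation and ribosomal protein genes were then called higher with CDA. Integrated stress and unfolded protein response genes were higher in 7 of 31 members, with a median of -0.11 (camera adjusted p = 0.00167, and adjusted p = 0.837 with an estimated correlation). The leucine sensor SESN2 stood at 614 ± 81.4 against 858 ± 437 and the pseudokinase TRIB3 at 1042 ± 278 against 1586 ± 950. SESN2 was at 1630 in CDA_E67Q pool 2 and at 609 to 781 in the other CDA_E67Q libraries. Autophagy and lysosome genes were higher in 4 of 27 members, with a median of -0.12 (camera adjusted p = 0.00605, and adjusted p = 0.837 with an estimated correlation). The lysosomal channel MCOLN1 stood at 449 ± 85.1 against 567 ± 130 and GPNMB at 14 ± 10.6 against 21.6 ± 10.4. Oxidative phosphorylation genes were higher in 8 of 51 members, with a median of -0.085 (camera adjusted p = 0.00647, and adjusted p = 0.875 with an estimated correlation). ATP5F1C stood at 4105 ± 637 against 4865 ± 1299 and COX7A2 at 2603 ± 484 against 2249 ± 223. Ribosomal protein genes were higher in 12 of 61 members, with a median of -0.049 (camera adjusted p = 0.0415, and adjusted p = 0.875 with an estimated correlation). RPS28 stood at 13983 ± 4611 against 16355 ± 4765 and RPL36 at 16673 ± 5190 against 18969 ± 5453. With pool number as a block the ribosomal call was lost (adjusted p = 0.0650).

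Here too the calls changed with the libraries in the fit, and some medians kept their size while others shrank or turned. The interferon call ended without CDA replicate 3 (median 0.10, adjusted p = 0.294) or 5 (median 0.049, adjusted p = 0.555). It also ended without CDA_E67Q replicate 3 (median 0.12, adjusted p = 0.127) or 4 (median 0.089, adjusted p = 0.543). The G1/S call ended without CDA replicate 1 (median 0.17, adjusted p = 0.107), 2 (median 0.062, adjusted p = 0.472), 3 (median 0.19, adjusted p = 0.0789) or 4 (median 0.076, adjusted p = 0.0974). It also ended without CDA_E67Q replicate 5 (median 0.052, adjusted p = 0.454) and with no low-value filter (0.0836). The histone call ended without CDA replicate 1 (adjusted p = 0.107), 2 (0.0581), 3 (0.425) or 4 (0.235) and CDA_E67Q replicate 3 (0.0823) or 5 (0.946), with equal totals (0.0616) and with a filter of 1 per M reads (0.111). The stress response call ended without CDA replicate 3 (adjusted p = 0.0608), 4 (0.0597) or 5 (median -0.14, adjusted p = 0.0520) and CDA_E67Q replicate 2 (0.420). The autophagy call ended without CDA replicate 3 (adjusted p = 0.181) or 4 (median -0.12, adjusted p = 0.0974) and CDA_E67Q replicate 1 (0.0555), 2 (0.397) or 5 (0.252). The oxidative phosphorylation call ended without CDA replicate 1 (adjusted p = 0.107) or 5 (0.777), and without CDA_E67Q replicate 2 the list was called higher with CDA (median 0.064, adjusted p = 0.0377). The ribosomal call ended without CDA replicate 1 (adjusted p = 0.637), 2 (0.472), 3 (median -0.062, adjusted p = 0.0789) or 4 (0.160) and CDA_E67Q replicate 3 (median -0.058, adjusted p = 0.0926) or 5 (0.825). Without CDA_E67Q replicate 2 that list was also called higher (median 0.069, adjusted p = 0.0174). It ended as well with equal totals (0.0616), no low-value filter (0.0836) and only the 10 libraries compared, without (0.0562) and with the block (0.116). Without pool 5 in every group 11 lists were called, and the histone list was not (0.0821).

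With all libraries and no block, the lists nearest to the enzyme did not separate CDA from CDA_E67Q by camera. With pool number as a block DNA replication genes were called higher with CDA (median 0.083, adjusted p = 0.00168, from 3.91e-11 to 0.983 over 24 alternatives, and adjusted p = 0.679 with the block and an estimated correlation). Their direction turned between leaving out CDA replicate 5 (median 0.35, adjusted p = 3.91e-11) and CDA_E67Q replicate 5 (median -0.15, adjusted p = 0.0135, called lower). NRF2 targets were then called lower (median -0.071, adjusted p = 0.0299, from 0.0248 to 0.972, and adjusted p = 0.647 with the block and an estimated correlation). Without the block DNA replication genes were higher with CDA in 35 of 48 members (adjusted p = 0.0771), with RFC1 at 2343 ± 175 against 2026 ± 225 and TOPBP1, an activator of the ATR kinase, at 3106 ± 783 against 2543 ± 607. Replication stress response genes were higher in 25 of 41 members (0.143), with FANCM at 295 ± 112 against 206 ± 57.2 and REV1 at 755 ± 87.1 against 639 ± 117. Homologous recombination genes were higher in 17 of 24 members (0.0924), with RAD51B at 162 ± 57.9 against 107 ± 14 and NBN at 547 ± 113 against 444 ± 121. Pyrimidine metabolism genes were higher in 14 of 28 members (0.965), with CAD at 5876 ± 461 against 6926 ± 1573 and the dNTP hydrolase SAMHD1 at 1128 ± 143 against 943 ± 351. Transport and efflux genes were higher in 4 of 12 members (0.0771), with SLC28A1 at 5.02 ± 3.88 against 11.6 ± 8.50 and ABCC10 at 651 ± 165 against 801 ± 251. For p53 targets 11 of 26 members were higher (0.803), with SESN2 as above and XPC at 967 ± 188 against 854 ± 328. Without pool 5 in every group DNA replication (0.000422), homologous recombination (0.00692), the replication stress response (0.0347), G2/M (9.77e-05) and, lower, NRF2 targets (0.0312) were gained. Homologous recombination and the replication stress response were also called higher without CDA replicate 5 (5.60e-05 and 6.29e-05), CDA_E67Q replicate 2 (0.0377 and 0.0431) or CDA_E67Q replicate 4 (0.0129 and 0.0426). Transport and efflux genes were called lower without CDA replicate 5 (0.0175) or CDA_E67Q replicate 2 (0.0376), and pyrimidine metabolism lower without CDA_E67Q replicate 5 (0.0472). The fits without 1 pool 5 library kept that of the other group. Pool 5 was high in transport and efflux genes (median 0.56 log2) and low in the other lists of those fits. Their calls therefore cannot be told from the pool 5 pattern. The remaining 16 lists were not called, from NRF2 targets (0.0763) to cholesterol biosynthesis (0.967). Median and mean differed in sign for epithelial markers, hypoxia and glycolysis, and cholesterol biosynthesis.

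No gene passed the threshold for CDA against CDA_E67Q. By limma 0 of 11588 genes were called, 24 had an unadjusted p under 0.05 (14 higher, 10 lower) where chance gives 579, and the groups did not overlap for 5 genes, 0.0431% against 0.794% by chance. Here too the chance values ignore pool number. Other splits gave a median of 375 genes under 0.05, and the real split gave 127 with pool number as a block. Of the list members, 0 passed when adjusted over all genes and 0 when adjusted over the list alone, and by fry 0 lists were called (smallest adjusted p = 0.972). Among low unadjusted p, 4 genes were chosen after their values were seen: EEPD1, a nuclease-family gene tied to stalled fork repair, at 249 ± 83.7 against 390 ± 70.7, MARCKS at 381 ± 711 against 15.9 ± 15.9, the clock repressor BHLHE41 at 308 ± 143 against 553 ± 151, and CTH of cysteine synthesis at 376 ± 126 against 599 ± 124. Their log2 differences were -0.70 (SE 0.253), 3.11 (SE 1.14), -0.97 (SE 0.357) and -0.72 (SE 0.285).

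**Figure D3:**
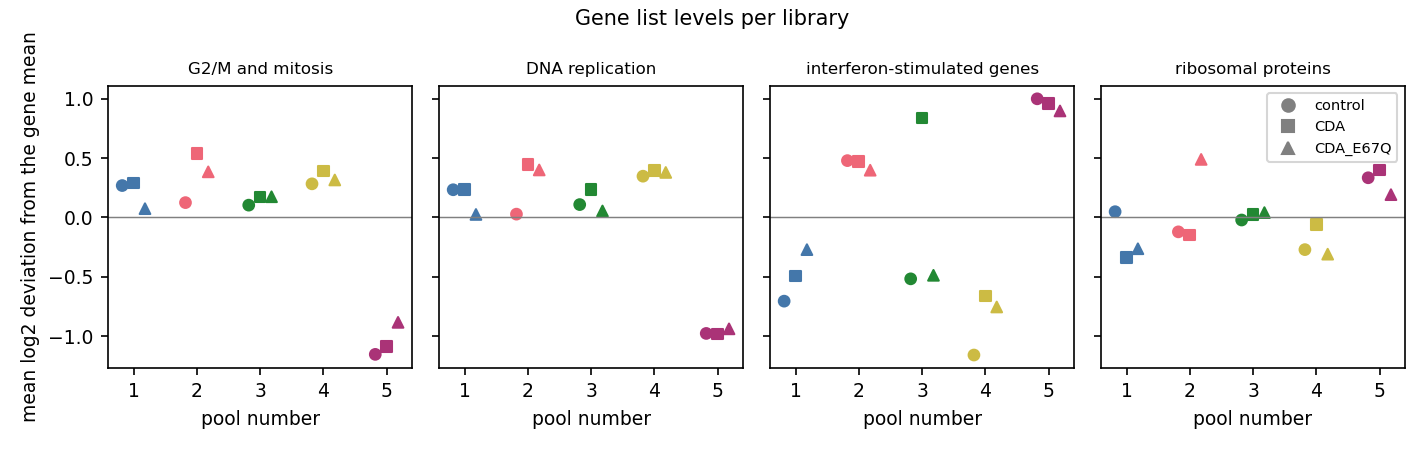
Mean log2 deviation from the gene mean, per library and pool number, for G2/M and mitosis, DNA replication, interferon-stimulated and ribosomal protein genes, with symbols for the 3 groups. Pool 5 is low in the first 2 lists in every group, and CDA pool 3 lies at 0.84 in the interferon list, against -0.52 in control pool 3 and -0.49 in CDA_E67Q pool 3.

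The responses to CDA and CDA_E67Q were compared over 11587 genes, leaving out CDA. Their log2 differences from the control had the same sign for 71.9% of genes, and correlated across genes at r = 0.65, with a covariance of 0.0601. Genes are not independent replicates, and both comparisons used the same controls. Unchanged groups, simulated by permuting the libraries 1000 times, gave a mean r of 0.496 (95th percentile 0.805) and a covariance of 0.104, so the observed covariance differed from it by -0.0437. With permutations within pool numbers, r averaged 0.491, the covariance averaged 0.0476, below the observed 0.0601, and 18.1% of permutations had an r as large. With the controls split between the comparisons, the median r over 20 splits was -0.23 (-0.33 to -0.047), with different pools in the 2 sets of controls. The 2 sets together make up all the controls, so they deviate from the control mean in opposite directions. Where pools differ, this pulls r down, so the negative r does not count against a shared response. The number of genes called in both was 0, as it was in each.

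Of the markers of other cell types, camera did not call the fibroblast, neuroendocrine, epithelial or mesenchymal lists in any comparison. The fibroblast marker TAGLN stood at 148 ± 79.9 with CDA and 61.0 ± 21.8 in the control, and the neuroendocrine marker SCG2 at a mean of 2945 and 6068, neither past the threshold. The mesenchymal filament gene VIM stood at a mean of 204528 with CDA and 180291 in the control, and the keratin KRT8 at 25006 and 23943. Immune, endothelial and acinar lists had 3, 3 and 1 tested genes and were not tested as lists. Their highest members were CD68 (738 with CDA, 636 in the control, and 857 with CDA_E67Q against 620), EGFL7 (3093 and 2928) and CEL (41.1 and 51.0). The list of mitochondrially encoded genes had fewer than 5 tested genes.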

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

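The tests of explanations in this part, and the splits of the libraries, were chosen only after the results were seen. In 187 groups of 5 values, 18 held a library far from the other 4 (a gap above 0.71 of the whole range), where chance gives 9.35, and 10 of the 18 were libraries of pool 5.

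In pool 5, mitotic and DNA replication genes were far below the other libraries of the same group. The mean deviation of G2/M genes was -1.08 log2 in CDA pool 5 (others 0.18 to 0.55) and -1.15 in control pool 5 (0.11 to 0.29), and that of DNA replication genes was -0.99 (0.23 to 0.44) and -0.99 (0.020 to 0.34). Histones were at -0.79 in CDA pool 5 (others 0.29 to 0.61). H1-5 was at 4.70 in CDA pool 5 (others 25.1 to 39.5) and 0.932 in control pool 5 (11.2 to 24.0), RFC4 at 1020.3 (1507 to 1647) and NBN at 348 (572 to 622) in CDA pool 5. The 10 most abundant genes held 9.65% of the counts of CDA pool 5 (others 6.41 to 6.98%).

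The values argue against library depth as the source of the pool 5 pattern: 0 of its 3 libraries had estimated reads outside the range of the other 12. A minor share of other cells could not lower a transcript much, yet 21 genes were at least 4-fold below every other library in all 3. Another cell line under that number may be an explanation and stays open: MTAP, listed at 0 in the other 12 libraries, had a mean of 0.636 there (highest 1.91), but a line that also lacks MTAP would look alike, so this cannot be told apart. No biological explanation was tested, because the labels give pool 5 no condition of its own.

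Control pool 1 correlated better with number 4 than with its own in both other groups, and control pool 4 did so with number 1 for CDA (r = 0.472 against 0.341), but not for CDA_E67Q (0.270 against 0.317). Genes that separated CDA and CDA_E67Q pools 1 and 4 put the controls on their own side for 29.4% of 211 genes, against 62.0 to 97.9% for other pairs of pools. An exchange of the 2 control libraries may account for this, but pool 4 as labelled already had 372 genes apart from the other 12 libraries, where chance gives 50.9, and 384 with the exchange. For pool 1 the counts were 68 and 373, so the exchange stays open. Outside the controls, CDA pool 1 correlated at -0.030 with CDA_E67Q pool 4, and CDA pool 4 at -0.156 with CDA_E67Q pool 1. Pairs of unlike number averaged -0.152 there, so these values argue against a likeness of the 2 pools in the CDA and CDA_E67Q libraries. An exchange would change no comparison between groups without a block.

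Differences between CDA and CDA_E67Q, called by camera at the preset correlation, had median log2 values of 0.25 for interferon-stimulated genes, 0.20 for CDK inhibitors and G1/S cyclins, 0.18 for histones, -0.11 for the integrated stress and unfolded protein responses, -0.12 for autophagy and lysosome, -0.085 for oxidative phosphorylation and -0.049 for ribosomal proteins. Over splits that ignore pool number chance can not be excluded: 52 of 100 gave at least 7 lists, the real one included (highest other 16), 53 of 100 at least the real 7 for CDA against control (highest other 17), and 99 of 100 at least the real 2 for CDA_E67Q against control (highest other 15). Only 16 splits part every same-numbered pair as the real one does, too few for a share under 0.05, and their highest other counts were 7, 8 and 10 lists against the real 7, 2 and 7, or 13, 11 and 12 against 8, 3 and 8 with the block (CDA, CDA_E67Q, then CDA against CDA_E67Q). For genes the real count was 0, which all 100 of 100 splits must reach, so that test says nothing on chance, and the highest other splits gave 6, 5 and 33. These highest splits, of genes and of lists, all put both pool 5 libraries on the same side, which points to the structure of pools.

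Other single libraries stood out by value alone. In the control group, CDT1 was at 2277 in pool 3 (others 2936 to 3081) and CAD at 3916 in pool 2 (5274 to 5392), and hypoxia genes deviated by 0.24 log2 in pool 2 (-0.22 to -0.092). In CDA_E67Q pool 2, SAMHD1 was at 366 (894 to 1252), SESN2 at 1630 (609 to 781), and the estimated depth was 29.1 M reads (21.4 to 23.0). In CDA_E67Q pool 3, TLR3 was at 3.75 (8.94 to 11.5) and GPNMB at 4.70 (20.6 to 31.2).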

How the results depend on the processing

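Tests with other pseudocounts, with deposited values, with combined settings (fry and an estimated correlation with the block among them) and without pool 5 were chosen only after the results were seen, as were those of scaling, filter and libraries in the fit for the lists. By limma 0 genes were called in each comparison (32, 54 and 24 at an unadjusted p under 0.05). In 66 of 70 alternatives 0 were called too, though those that only add a minimum of 1.5-fold or 2-fold could call none. In 4 alternatives 1 gene was called, CDA itself. These were the deposited values with replicate block (1 gene with CDA, log2 2.94, and 1 with CDA_E67Q, 3.50) and all 15 libraries with replicate block (1 with CDA, 4.71, and 1 with CDA_E67Q, 5.09). Over 22 alternatives the adjusted p of CDA ran from 0.00220 to 1.00 with CDA and from 0.00111 to 1.00 with CDA_E67Q, and without single libraries the log2 values ran from 4.06 to 5.28 and 4.44 to 5.65 (-0.78 to -0.052 between the forms). Lists called were 7, 2 and 7, in the order CDA and CDA_E67Q against control and CDA against CDA_E67Q, but 0, 0 and 0 with an estimated correlation and 0, 0 and 0 by fry. Without a low-value filter 2, 1 and 5 were called. For CDA_E67Q 1 was called under upper-quartile scaling, 1 with equal totals, 5 with deposited values and block, and 4 with all 15 libraries and block. Without pool 5 the counts were 7, 3 and 11. Without single libraries they ran from 2 (without CDA replicate 4) to 12 (CDA replicate 5), from 2 (control replicate 3) to 8 (CDA_E67Q replicate 5), and from 1 (CDA replicate 3) to 12 (CDA_E67Q replicate 2). Medians that changed sign without a library ran, for CDA, from -0.13 to 0.44 (G2/M), -0.12 to 0.36 (DNA replication) and -0.031 to 0.19 (MYC), for CDA_E67Q from -0.053 to 0.22 (oxidative phosphorylation), and between the forms from -0.15 to 0.069 (ribosomal), -0.21 to 0.064 (oxidative phosphorylation) and -0.050 to 0.47 (histones). Lists not called with all libraries were called in both directions by leaving out 1 pool 5 library, which leaves that of the other group in the fit. For CDA_E67Q these were G2/M (-0.19 and 0.31) and DNA replication (-0.20 and 0.26), and between the forms DNA replication (-0.15 and 0.35) and G2/M (-0.18 and 0.34). Ribosomal proteins also turned, for CDA (-0.14 without CDA replicate 5, 0.061 without control replicate 5) and for CDA_E67Q (-0.089 without CDA_E67Q replicate 2, 0.13 without control replicate 5). SLC29A2 ran from -0.20 to 0.041 with CDA. The correlation of both responses was -0.23 with the controls split, a split that itself pulls r down. Fits that leave out 1 pool 5 library compare unequal sets of pools, so their calls cannot be told from the pool 5 pattern. Apart from the split of the controls, the cause of the changes above was not tested. Of the values of named genes, 1713 of 1714 kept direction and side of the threshold. None of these genes had passed the threshold with all libraries, so keeping the side tells little. Their direction was read in largely the same libraries from which they were chosen.

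Of same-numbered pairs with control, 4 of 5 correlated above 0.1 with CDA and 4 of 5 with CDA_E67Q (pool 1 at 0.011 and -0.060, highest 0.887 and 0.878, mean of other pairs -0.091 and -0.092), and 6 and 7 of 10 libraries correlated best with their own number. With pool number as a replicate block 0 genes were called in each comparison (201, 265 and 127 at an unadjusted p under 0.05), CDA had adjusted p = 0.0676 and 0.0691, and 8, 3 and 8 lists were called, but 0, 0 and 0 with the block and an estimated correlation and 0, 0 and 0 by fry with the block. Between CDA and CDA_E67Q the block ended the ribosomal call and gained DNA replication and NRF2 targets. It gained the integrated stress response for CDA and G2/M for CDA_E67Q. Tests on counts and their normalisations, voom, and removal of CDA before normalisation were not run, because the values are not counts. Deposited values were not used between the forms, whose tables have separate scales. Depth is only estimated, so no counting limit can be given.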

Other observations

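The comparisons of pools and of single libraries in this part were all chosen after the data were seen, and p-values are limma's. Pool 5 differed from the other 12 libraries in 4777 of 11588 genes (2325 higher, 2452 lower), and its 3 libraries lay apart for 34.2% of genes where chance gives 0.44%. G2/M and mitosis genes were lower in 38 of 39 members, 38 past the threshold, with a median of -1.37 log2 (camera adjusted p = 2.01e-23, and adjusted p = 0.0682 with an estimated correlation). DNA replication genes were lower in 48 of 48, 43 past the threshold, with a median of -1.10 (6.42e-20, and adjusted p = 0.0682 with an estimated correlation). Homologous recombination genes fell in 16 of 24 members and rose in 1 (adjusted p = 0.234 with an estimated correlation), and replication stress genes fell in 23 of 41 and rose in 3 (0.0682). Interferon-stimulated genes rose in 18 of 41 members and fell in 2, with a median of 1.14 (3.84e-05, and adjusted p = 0.426 with an estimated correlation), and NF-kB and cytokine genes rose in 11 of 21 and fell in 2 (adjusted p = 0.234 with an estimated correlation). By fry the adjusted p was 3.02e-07 for G2/M, 6.27e-07 for DNA replication and for replication stress, and 7.14e-05 for homologous recombination. It was 0.0115 for interferon-stimulated and 0.000202 for NF-kB and cytokine genes. Many other lists passed by fry too, such as epithelial markers (0.000143) and p53 targets (0.0276), though not cholesterol biosynthesis (0.173). With 4777 of 11588 genes called, fry therefore does not single out the lists named here. The collagenase MMP1 was at 24678 ± 4010 in pool 5 (SD, 3 libraries) against 4.76 ± 6.94, the prostaglandin synthase PTGDS at 3297 ± 865 against 15.0 ± 14, mesothelin MSLN at 431 ± 108 against 4.58 ± 5.30, and xanthine dehydrogenase XDH at 5.34 ± 2.99 against 461 ± 368. These genes were picked for their size of difference.

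Single genes also marked the other pools. They were picked from called genes whose 3 libraries all lay beyond the other 12, so their likeness across the 3 groups follows from that choice. In pool 2, LAPTM5 was at 11141 ± 6413 against 104 ± 166, IL18 at 296 ± 182 against 8.83 ± 9.76 and EPAS1 at 685 ± 127 against 56.1 ± 41.1. In pool 3, FOXQ1 was at 1127 ± 169 against 155 ± 73.7, while the growth factor VEGFC was at 12.1 ± 10.1 against 1142 ± 428 and the WNT inhibitor DKK1 at 11 ± 8.54 against 924 ± 507. Cholesterol biosynthesis genes were higher in pool 3 in 18 of 22 members and fatty acid synthesis genes in 15 of 15. By camera with an estimated correlation their adjusted p was 0.0301 and 0.0474, adjusted over the lists of pool 3 alone. The same lists were tested in every pool, and these were picked after the results were seen. No adjustment over all pools was made, so these values do not show that the calls hold. The other 12 libraries also fall into pools, so they are not independent of each other. In pool 4 the immediate early genes EGR1 (4288 ± 847 against 19105 ± 5652), ZFP36 (179 ± 27.0 against 1366 ± 542) and NR4A1 (32.3 ± 22.1 against 435 ± 357) were lower, picked from the called genes. The list of immediate early and heat shock genes holds EGR1 and NR4A1 but not ZFP36. As a whole it had 11 members higher and 10 lower there (median 0.048). Of its members 3 were called lower (EGR1, EGR2 and NR4A1) and 0 higher. Camera called the list lower (adjusted p = 0.000281, and adjusted p = 0.530 with an estimated correlation). Interferon-stimulated genes were lower there in 41 of 41 members, with a median of -1.04 (camera adjusted p = 9.27e-13, and adjusted p = 0.455 with an estimated correlation). In pool 1, SHROOM3 was at 36.9 ± 12.3 against 888 ± 597. The counts of genes called were 2, 37, 23 and 6 for pools 1 to 4. The 3 libraries lay apart for 0.587, 3.32, 2.09 and 3.21% of genes, where chance gives 0.44%, so pool 1 was near chance.

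Within pool 3 the CDA library had an interferon score of 0.84 log2, against -0.52 in the control and -0.49 in CDA_E67Q, and 31 of 41 genes lay above both. ISG15 was at 2409 there, against 326 in the control and 599 in CDA_E67Q, RSAD2 at 313 against 14.2 and 37.5, and OAS2 at 174 against 28.8 and 39.5, while MX1 at 30.3 lay between 19.3 and 48.0. These genes were picked after their values were seen. Within pool 2 the CDA_E67Q library had 55 of 61 ribosomal protein genes and 26 of 30 MYC target genes above both other libraries. These libraries were picked for their size of difference and have no replicate, and no explanation was tested.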
